A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

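Total RNA of 12 yeast cultures, 3 of each of 4 strains, was measured on Affymetrix Yeast Genome 2.0 arrays. Per the labels' protocols, cells grew at 30 °C in rich medium with 5% glucose to an OD600 of 0.7 to 1.3, RNA was extracted with hot acid phenol, and 250 ng were amplified and labelled with a 3' IVT Express kit. The deposited values are log2 signal intensities made with RMA in the affy package, per the submitters' processing notes; versions are not given in the sources used here. The base of the logarithm is not stated; base 2 was inferred from RMA and from values between 3.4 and 14.9. The table used here held 5715 probe sets on 12 arrays, and no further transformation or normalization was applied.

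Groups follow the genotype labels. For the hdac and combined arrays the source name gives the strain names the other way round, and the signals of the deleted genes were checked against the genotype labels. Of the probe sets, 5497 had 1 gene symbol, 0 had several and 218 had none; 12 symbols were updated through Entrez identifiers. For genes with several probe sets the one with the highest mean was kept (49 dropped), which left 5448 genes, 100 of them read by probe sets ending in _s_at and 18 by ones ending in _x_at. Those can cross-hybridize, so values of near-identical genes (HXT7, MAL32, PHO11, seripauperins, ribosomal proteins, COS genes, flocculins, HMLALPHA1 with MATALPHA1, HMRA1 with MATA1) are uncertain as to the copy. The genome build of the array is not given in the sources used here and no coordinates are printed. The planned background from S. pombe probe sets could not be taken from the table used here. Instead the highest of 18 values of BMH2, HDA1 and RPD3 on arrays of strains that lack them, 4.13 (lowest 3.68, median 3.82), was used; this was chosen after the values were seen. Means at or below it were found for 95 genes in the wild type, 80 in the bmh, 110 in the hdac and 113 in the combined mutant, and for 57 in all strains. For a gene at background in 1 strain the change is given as a lower bound, from the background to the mean of the other strain.

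Differences were tested with limma 3.58.1 (R 4.3.3, statmod 1.5.0): a means model of the 4 groups on all 12 arrays, lmFit and eBayes with default settings, 8 residual and 3.82 prior degrees of freedom, and Benjamini-Hochberg adjustment over the 5448 genes. A gene was called changed at adjusted p under 0.05, at any size of change. Deviations from the strain means were checked for pairing by replicate number: for the bmh and combined arrays, same-numbered arrays correlated at 0.135, 0.100 and 0.129 and differently numbered ones between −0.106 and −0.0306, so these were also fitted as pairs; the pairing comes from the data and not from the labels. There were 5 pairwise comparisons and the interaction, combined minus bmh minus hdac plus wild type. Simulations (200 changed genes, 20 repeats) had log2 changes of 0.25, 0.5, 1 and 2. The bmh comparison recovered 25.9, 89.6, 99.7 and 100%, with 5.17% false calls, and the interaction 6.7, 58.7, 97.3 and 99.8%, with 4.93%. The real arrays, with more wild-type spread, may differ.

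Gene lists were fixed before the values were opened, 38 in all, and every list was tested. Those reported cover Adr1-dependent genes, gluconeogenesis, beta-oxidation, sugar use, hexose transport, glycolysis, TCA cycle, respiratory chain, Msn2/4 stress, glycogen, Hsf1 chaperones, ribosomal proteins, ribosome biogenesis, early meiosis, sporulation, phosphate, phospholipid, retrograde, nitrogen, Gcn4, sulfur, purine, iron, DNA damage, a-cell, alpha-cell, pheromone, seripauperin, flocculin, COS, histone, G1, G2/M, cell wall, ergosterol, deacetylase subunit and strain marker genes. The main test was camera with its preset correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were run beside it. Genes are named by rule: the 4 mutated genes; the 10 largest rises and falls (5 for the comparisons with the bmh or hdac mutant and for the interaction) that were called, had non-overlapping groups in pairwise comparisons and lay above background in a compared group; up to 4 called members of each described list with the largest change; and ADH2 with the other Adr1-dependent genes. The result of 1 list and of 1 gene that this rule names is not reported. Genes of NAD synthesis, AFB1 and HMRA2 outside this rule were chosen after the values were seen. Alternatives tried were quantile normalization, median centring, filters on dim genes, trend and robust eBayes, fits of 2 groups, array weights, a replicate block, all probe sets, no shared probe sets, adjusted p under 0.01, and leaving out each array.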

Results

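Messenger RNA of budding yeast (Saccharomyces cerevisiae) was measured on 12 Affymetrix Yeast Genome 2.0 arrays, 3 for each of 4 strains. The strains were the wild type W303-1A, a common laboratory strain; the bmh mutant, which carries a temperature-sensitive allele of BMH1 and lacks BMH2, the genes of the yeast 14-3-3 proteins that bind phosphorylated partners; the hdac mutant, which lacks HDA1 and RPD3, the catalytic subunits of histone deacetylase complexes; and the combined mutant, which carries all of these mutations. All cultures grew exponentially at 30 °C in rich medium with 5% glucose, a condition in which genes for the use of other carbon sources are repressed. The design asks how reduced 14-3-3 function and loss of the deacetylases change expression under glucose repression, separately and together. Array medians lay between 8.806 and 8.846 on the log2 scale, and 3 arrays per strain limit the precision. The replicates are triplicate cultures, and p-values use a spread per gene pooled over strains. Changes are given as log2 differences with their standard error, n = 3 per strain, and adjusted p-values are those of limma with Benjamini-Hochberg adjustment.

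The deleted genes were at background where the genotype labels say they are absent. BMH2 measured 11.64 ± 0.17 (mean ± SD, n = 3) in the wild type and 11.65 ± 0.055 in the hdac mutant, against 4.03 ± 0.12 in the bmh mutant and 3.80 ± 0.023 in the combined mutant. HDA1 measured 8.22 ± 0.029 in the wild type and 8.28 ± 0.12 in the bmh mutant, against 3.82 ± 0.018 and 3.78 ± 0.092 in the hdac and combined mutants, and RPD3 measured 9.61 ± 0.097 and 9.73 ± 0.027 against 3.86 ± 0.087 and 3.89 ± 0.18. Taking the highest value of a deleted gene, 4.13, as the background, these were falls of at least 182-fold for BMH2, at least 17-fold for HDA1 and at least 44.6-fold for RPD3. BMH1 RNA lay between 12.71 and 12.93 in all 4 strains; its mutant allele need not change the RNA, so this level checks no label. ADH2, the glucose-repressed alcohol dehydrogenase that consumes ethanol, measured 7.39 ± 0.41 in the wild type, 9.95 ± 0.27 in the bmh mutant, 9.21 ± 0.062 in the hdac mutant and 13.94 ± 0.020 in the combined mutant.

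**Figure D1:**
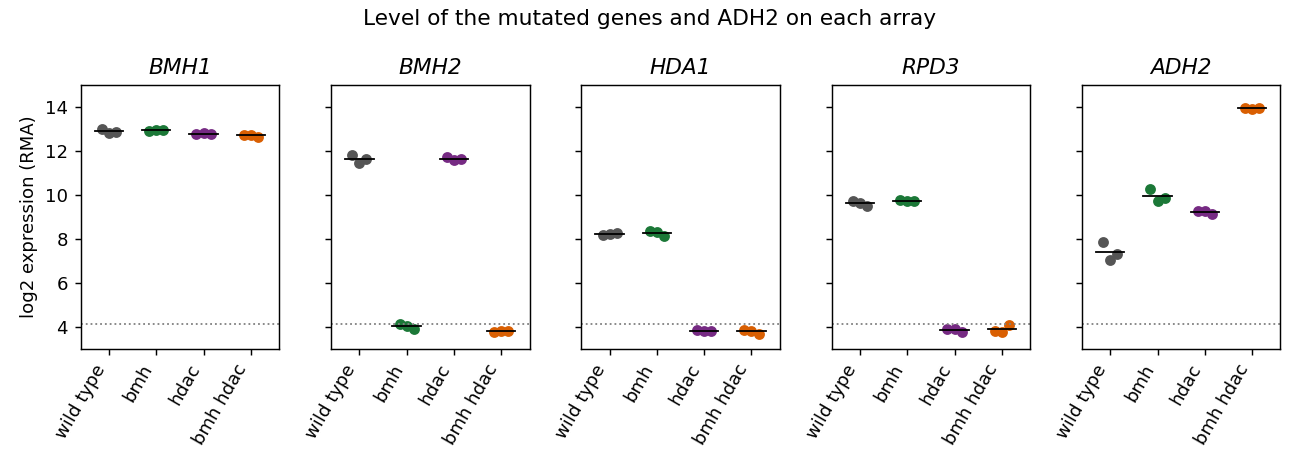
Log2 expression (vertical axis, RMA values) of the 4 mutated genes and ADH2 on each of the 12 arrays; points are arrays, black lines are strain means and the dotted line is the background at 4.13. BMH2, HDA1 and RPD3 sit at the dotted line in the strains that lack them, and ADH2 reaches 13.94 in the combined mutant.

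The first principal component of the 12 arrays held 73.3% of the variance and separated the strains without HDA1 and RPD3 from the others, and the next held 15.4%. Of 5448 genes tested, 1742 (32.0%) changed in the bmh mutant, 3892 (71.4%) in the hdac mutant and 4122 (75.7%) in the combined mutant relative to the wild type. Changes of at least 2-fold numbered 153, 733 and 972. Replicates of the mutants lay close together, with a median SD over genes of 0.0654 to 0.0681, and the wild-type arrays were more spread, with 0.135. Wild-type array 1 differed at least 2-fold from the mean of the other wild-type arrays at 61 genes, against 5 and 6 genes for those arrays.

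The bmh mutant was compared with the wild type. This comparison varies 14-3-3 function, but marker genotype may differ too, as strain marker genes changed. The largest rises were in HIS3 (4.58 ± 0.063, adjusted p = 1.4e-13), a histidine synthesis gene used as a strain marker, in PIR3 (4.21 ± 0.19), a structural protein of the cell wall, and in HSP12 (3.81 ± 0.50), a stress-induced membrane protein. HSP12 stood 2.52 higher on wild-type array 1; without that array HSP12 was at 4.65, HIS3 at 4.63 and PIR3 at 4.49. YRO2 (3.65 ± 0.24), the purine enzyme ADE17 (3.02 ± 0.10), the vitamin B6 synthesis gene SNO1 (2.93 ± 0.16), the carbonic anhydrase NCE103 (2.85 ± 0.15), the mannoprotein HPF1 (2.82 ± 0.17), the secreted glycoprotein YGP1 (2.69 ± 0.18) and YJL218W (2.67 ± 0.069) followed. Apart from the deleted BMH2, the largest falls were in the peptide transporter PTR2 (−3.97 ± 0.16, adjusted p = 4.2e-09), the iron uptake genes FET3 (−3.36 ± 0.19), FRE4 (−3.05 ± 0.10) and FTR1 (−2.38 ± 0.19), and the phosphate starvation genes SPL2 (−3.26 ± 0.12), PHO11 (−2.66 ± 0.15) and PHO5 (−2.53 ± 0.13). The branched-chain aminotransferase BAT2 (−2.39 ± 0.12) and YAR068W (−2.36 ± 0.079) also fell. ADH2 rose by 2.56 ± 0.17 (adjusted p = 3.7e-07). In all, 807 genes rose and 935 fell, 89 and 64 of them at least 2-fold. With only these 6 arrays in the fit the count was 1093, and at adjusted p under 0.01 it was 1076.

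Cell wall genes rose together in the bmh mutant: 15 of 20 measured genes rose and 0 fell (15 and 0 adjusted over the list alone), among them PIR3 (4.21), KDX1 (2.56), CWP1 (1.53) and PST1 (1.25). The cell wall list gave adjusted p = 7.8e-09, and 0.16 with an estimated correlation. Of the genes for amino acid synthesis under Gcn4, 20 of 31 rose and 2 fell (20 and 2 adjusted over the list alone), with SNO1 (2.93), ARG1 (2.42), SNZ1 (1.92) and HIS4 (1.67). The Gcn4 list gave adjusted p = 7.8e-09, and 0.19 with an estimated correlation. Of the purine synthesis genes 10 of 17 rose and 3 fell (10 and 3 adjusted over the list alone); ADE17, ADE1 (1.65) and MTD1 (1.47) rose and the IMP dehydrogenase IMD2 (−1.27) fell. The purine list gave adjusted p = 7.6e-04, and 0.33 with an estimated correlation. Marker genes moved as well: HIS3 (4.58), ADE2 (1.52), URA3 (1.45) and LEU2 (0.76) rose, and in that list 6 of 7 rose and 1 fell (6 and 1 adjusted over the list alone). The marker list gave adjusted p = 5.9e-05, and 0.070 with an estimated correlation. Of the genes under nitrogen catabolite repression 13 of 26 rose and 2 fell (14 and 3 adjusted over the list alone), with MEP2 (1.57), UGA2 (1.36), DIP5 (1.32) and PUT4 (1.19). The nitrogen list gave adjusted p = 1.9e-04, and 0.19 with an estimated correlation. Of the inositol-regulated phospholipid genes 7 of 13 rose and 1 fell (8 and 1 adjusted over the list alone), with OPI3 (1.21), CHO1 (0.64), ITR1 (0.60) and CKI1 (0.57). The phospholipid list gave adjusted p = 0.0028, and 0.33 with an estimated correlation. Of the flocculins 4 of 5 rose and 0 fell (4 and 0 adjusted over the list alone), with FLO10 (0.58), FLO11 (0.50), FLO8 (0.38) and FLO9 (0.27). The flocculin list gave adjusted p = 0.0056, and 0.33 with an estimated correlation.

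Phosphate starvation genes fell, 1 of 13 measured genes rose and 12 fell (1 and 12 adjusted over the list alone), with SPL2 (−3.26), PHO11 (−2.66), PHO5 (−2.53) and PHM6 (−2.13). The phosphate list gave adjusted p = 8.7e-08, and 0.31 with an estimated correlation. Of the iron uptake genes under Aft1 1 of 17 rose and 10 fell (1 and 14 adjusted over the list alone), with FET3 (−3.36), FTR1 (−2.38), SIT1 (−1.40) and FRE1 (−1.34). The iron list gave adjusted p = 5.2e-05, and 0.33 with an estimated correlation; it stood 0.35 higher on wild-type array 1 than on the other wild-type arrays. Of the Hsf1 chaperones 0 of 18 rose and 9 fell (0 and 10 adjusted over the list alone), with BTN2 (−1.40), HSP82 (−1.08), CUR1 (−0.91) and SIS1 (−0.83). The chaperone list gave adjusted p = 0.0034, and 0.33 with an estimated correlation. The 9 falls were 5 without wild-type array 3 or bmh array 1 and 4 without bmh array 3. Of the ergosterol genes 0 of 23 rose and 9 fell (0 and 11 adjusted over the list alone), with ERG1 (−0.62), ERG27 (−0.54), ERG3 (−0.50) and ERG11 (−0.45). The ergosterol list gave adjusted p = 0.025, and 0.33 with an estimated correlation. Of the cytosolic ribosomal proteins 0 of 127 rose and 11 fell (0 and 4 adjusted over the list alone), with a median of −0.07 and RPS27A at −0.35. The ribosomal protein list gave adjusted p = 3.2e-04, and 0.60 with an estimated correlation. Quantile normalization of the arrays ended this call, and the 11 falls were 7 without wild-type array 3 and 4 without any 1 bmh array.

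Several groups called in the bmh mutant also stood apart on wild-type array 1. Of the Msn2/4 stress genes 12 of 28 rose and 0 fell (14 and 1 adjusted over the list alone), with HSP12 (3.81), YGP1 (2.69), MSC1 (1.98) and XBP1 (1.15). The stress list gave adjusted p = 1.4e-04, and 0.42 with an estimated correlation. On wild-type array 1 the median of this list was 0.32 above the other wild-type arrays. Of the retrograde response genes, which respond to the state of the mitochondria, 5 of 7 rose and 0 fell (6 and 0 adjusted over the list alone), with PYC1 (1.92), IDH1 (1.43), CIT2 (1.41) and IDH2 (1.39). The retrograde list gave adjusted p = 3.1e-04, and 0.33 with an estimated correlation, and wild-type array 1 stood 1.05 above the others. Of the tricarboxylic acid (TCA) cycle genes 7 of 16 rose and 0 fell (8 and 0 adjusted over the list alone), with IDH1 (1.43), IDH2 (1.39), ACO1 (1.09) and LSC2 (0.99). The TCA cycle list gave adjusted p = 0.0068, and 0.73 with an estimated correlation, and wild-type array 1 stood 0.45 above the others. Without wild-type array 1 12 rose and the median of 0.26 was 0.44, and without wild-type array 3 the call ended (adjusted p = 0.084) and the median was 0.15. Of the respiratory chain and ATP synthase genes 14 of 34 rose and 1 fell (20 and 1 adjusted over the list alone), with CYC7 (2.34), NDE1 (0.84), CYC1 (0.68) and QCR10 (0.66). The respiratory chain list gave adjusted p = 7.8e-06, and 0.57 with an estimated correlation. Its median on wild-type array 1 was 0.26 relative to the other wild-type arrays; 27 genes rose without that array and 9 without wild-type array 2, wild-type array 3 or bmh array 1. Of the sulfur and methionine genes 1 of 24 rose and 7 fell (1 and 7 adjusted over the list alone), with MET14 (−1.38), MET5 (−0.95), MET3 (−0.86) and MMP1 (−0.78). The sulfur list gave adjusted p = 0.020, and 0.75 with an estimated correlation. They stood 0.61 higher on wild-type array 1, and without it the call ended (adjusted p = 0.39) and the median of −0.27 was −0.03. Of the seripauperins 0 of 19 rose and 7 fell (0 and 9 adjusted over the list alone), with TIR1 (−2.19), PAU8 (−0.80), PAU18 (−0.72) and PAU14 (−0.68). The seripauperin list gave adjusted p = 0.026, and 0.73 with an estimated correlation. Its median on wild-type array 1 was −0.45 relative to the other wild-type arrays, and the call ended without wild-type array 2 (adjusted p = 0.19). The 7 falls were 11 without wild-type array 1, 2 without wild-type array 2, 3 without bmh array 1 or 2, and 4 without bmh array 3, any 1 combined array, hdac array 1 or hdac array 3.

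Of the Adr1-dependent genes, the targets of the activator Adr1 that glucose represses, 7 of 20 rose and 4 fell (7 and 4 adjusted over the list alone) in the bmh mutant, and the list as a whole did not pass (adjusted p = 0.49). Besides ADH2, the genes ALD4 (1.37), POT1 (0.52), ICL2 (0.45), SPS19 (0.40), FDH1 (0.37) and ADH5 (0.36) rose and PXA1 (−1.14), ATO3 (−0.95), FOX2 (−0.38) and GUT1 (−0.29) fell. The values of POX1 (0.23), RGI2 (0.11), ACS1 (0.09), CIT3 (0.06), PIP2 (−0.01), ADY2 (−0.08), CTA1 (−0.10), GIP2 (−0.11) and ETR1 (−0.25) did not pass. The beta-oxidation (adjusted p = 0.87), sugar-use (adjusted p = 0.71) and hexose transport (adjusted p = 0.66) lists did not pass. Of the gluconeogenesis and glyoxylate genes 6 of 11 rose and 2 fell (6 and 3 adjusted over the list alone), with MDH2 (1.48), CIT2 (1.41), IDP2 (0.49) and FBP1 (0.36). The gluconeogenesis list gave adjusted p = 0.045, and 0.33 with an estimated correlation. The call ended without wild-type array 1 (adjusted p = 0.13), wild-type array 3 (adjusted p = 0.059), bmh array 2 (adjusted p = 0.092) or bmh array 3 (adjusted p = 0.054), and under quantile normalization. The a-cell markers showed 3 falls among 7 genes, ASG7 (−0.59), MFA1 (−0.59) and STE6 (−0.35), and 0 rises (0 rises and 3 falls adjusted over the list alone; adjusted p = 0.045, and 0.31 with an estimated correlation); this call ended without wild-type array 1 (adjusted p = 0.076), wild-type array 2 (adjusted p = 0.067), bmh array 1 (adjusted p = 0.073) or bmh array 2 (adjusted p = 0.061). Calls of single genes named here that ended when 1 array was left out were those of ADH5 (2 of 12 arrays; adjusted p = 0.081 without bmh array 2), BTN2 (4 of 12 arrays; adjusted p = 0.095 without wild-type array 3), CUR1 (11 of 12 arrays; adjusted p = 0.14 without wild-type array 3), DIP5 (3 of 12 arrays; adjusted p = 0.072 without wild-type array 2), FBP1 (1 of 12 arrays; adjusted p = 0.051 without bmh array 3), FDH1 (5 of 12 arrays; adjusted p = 0.12 without bmh array 1), MMP1 (9 of 12 arrays; adjusted p = 0.11 without bmh array 3), PAU8 (10 of 12 arrays; adjusted p = 0.15 without wild-type array 3), PAU14 (11 of 12 arrays; adjusted p = 0.17 without wild-type array 2) and PAU18 (2 of 12 arrays; adjusted p = 0.066 without bmh array 2). With wild-type array 1 left out CTA1 fell (−0.44, adjusted p = 0.0068), and ADH5 was 0.21, BTN2 −2.10, DIP5 1.96, CUR1 −1.41, MMP1 −0.34, PAU8 −1.22 and PAU14 −1.07; without wild-type array 3 BTN2 was −0.93. None of the 20 list calls of this comparison held with an estimated correlation, and the other 18 lists did not pass (adjusted p from 0.376 to 0.897). The median, the mean and the direction of the test differed in sign for hexose transport, glycogen and trehalose, early meiosis (Ume6-repressed), middle and late sporulation and G1 cell cycle, none of which passed. With the background as the floor, the changes were at least 1.90-fold for XBP1.

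The hdac mutant was compared with the wild type, and marker genotype may again differ. The alpha-factor gene MF(ALPHA)1 (7.61 ± 0.078), the alpha1 regulator read by the HMLALPHA1 probe set (6.54 ± 0.060) and the a-factor receptor STE3 (4.53 ± 0.096, adjusted p = 2.6e-12) rose, while the a-factor gene MFA2 (−7.00 ± 0.080, adjusted p = 7.8e-15), the alpha-factor receptor STE2 (−6.74 ± 0.075), the protease BAR1 (−6.01 ± 0.094), the a-factor gene MFA1 (−4.48 ± 0.11), the a1 regulator read by the HMRA1 probe set (−4.44 ± 0.086), the agglutinin subunit AGA2 (−4.15 ± 0.076) and the a-factor exporter STE6 (−4.02 ± 0.066) fell. As MF(ALPHA)1 and HMLALPHA1 were at background in the wild type and HMRA1 in the hdac mutant, these were changes of at least 182-fold, at least 81.3-fold and at least 13.9-fold. The other large rises were in SNO1 (5.64 ± 0.16), the epoxide hydrolase YNR064C (5.21 ± 0.18), the sporulation glucoamylase SGA1 (5.00 ± 0.072), PIR3 (4.65 ± 0.19), HPF1 (4.58 ± 0.17), the lipid transporter RSB1 (4.45 ± 0.13) and the inositol synthesis gene INO1 (4.18 ± 0.21). BNA1 (−4.66 ± 0.092), an enzyme of NAD synthesis from tryptophan, fell as well. ADH2 rose by 1.82 ± 0.17 (adjusted p = 1.5e-06). In all, 1624 genes rose and 2268 fell, 480 and 253 of them at least 2-fold.

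**Figure D2:**
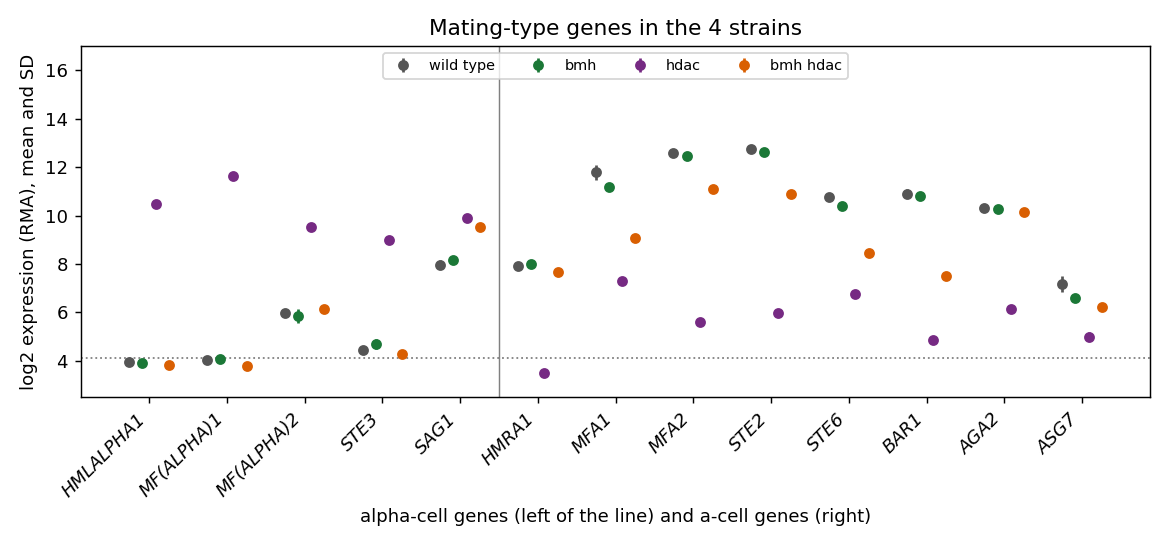
Mean log2 expression (vertical axis, error bars are SD, n = 3 arrays) of genes of alpha cells and of a cells in the 4 strains; the dotted line is the background at 4.13. MF(ALPHA)1 is at 11.64 in the hdac mutant and at or below 4.10 in the other strains, and STE2 is at 5.996 in the hdac mutant and 10.88 or above in the others.

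All 7 a-cell markers fell and all 4 alpha-cell markers rose, each with the same counts adjusted over the list alone. The a-cell list gave adjusted p = 2.4e-06 and the alpha-cell list adjusted p = 1.4e-04. This strain differed from the wild type in its mating-type transcripts as well as in its deacetylases. Of the pheromone response and mating genes 2 of 19 rose and 15 fell (2 and 15 adjusted over the list alone); SST2 (−2.16), FUS1 (−1.71) and GPA1 (−1.50) fell and FIG2 (1.56) rose. The pheromone list gave adjusted p = 0.0057, and 0.055 with an estimated correlation. Genes of early meiosis, which Ume6 represses by recruiting Rpd3, rose: 21 of 23 measured genes rose and 0 fell (21 and 0 adjusted over the list alone), with IME2 (3.02), MND1 (2.68), DMC1 (2.08) and HOP1 (1.92). The early meiosis list gave adjusted p = 7.0e-08. The middle and late sporulation list did not pass against other genes by camera (adjusted p = 0.087). Of its genes 2 of 23 rose and 11 fell (2 and 11 adjusted over the list alone), with SSP1 (−2.48), SPO21 (−2.01) and SPS4 (−1.82) falling and SPS100 (2.37) rising. Of the DNA damage genes 11 of 16 rose and 1 fell (11 and 1 adjusted over the list alone), with RNR3 (3.10), HUG1 (1.91), DDR48 (1.53) and DUN1 (0.83). The DNA damage list gave adjusted p = 0.0011.

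Glucose-repressed groups rose in the hdac mutant. Of the Adr1-dependent genes 15 of 20 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.76. The Adr1 list gave adjusted p = 7.2e-05. The risen members were POT1 (4.17), ADY2 (3.04), ALD4 (2.65), ACS1 (1.85), ADH2 (1.82), POX1 (1.66), SPS19 (1.42), PIP2 (1.16), ICL2 (1.12), ADH5 (0.85), FOX2 (0.67), ETR1 (0.64), FDH1 (0.64), GUT1 (0.34) and RGI2 (0.32), ATO3 (−1.26) fell, and GIP2 (0.09), PXA1 (−0.07), CIT3 (−0.10) and CTA1 (−0.41) did not pass. Without wild-type array 1 CTA1 (−0.75, adjusted p = 4.5e-05) and CIT3 (−0.29, adjusted p = 0.036) fell. Of the gluconeogenesis and glyoxylate genes 10 of 11 rose and 0 fell (10 and 0 adjusted over the list alone), with SFC1 (3.11), JEN1 (2.59), CIT2 (2.37) and FBP1 (2.05). The gluconeogenesis list gave adjusted p = 5.2e-06. Of the peroxisomal beta-oxidation genes 14 of 19 rose and 2 fell (14 and 2 adjusted over the list alone), with POT1, POX1, CRC1 (3.72) and CAT2 (1.95). The beta-oxidation list gave adjusted p = 7.4e-05. Of the genes for sucrose, galactose and maltose use 11 of 14 rose and 1 fell (11 and 1 adjusted over the list alone), with MAL32 (2.13), MAL11 (1.66), GAL3 (1.35) and IMA1 (1.28). The sugar-use list gave adjusted p = 5.7e-04, and 0.10 with an estimated correlation. Of the hexose transport genes 10 of 15 rose and 3 fell (10 and 4 adjusted over the list alone), with HXT5 (3.83), HXT9 (2.63), STL1 (2.39) and HXT11 (1.78). The hexose transport list gave adjusted p = 0.013, and 0.25 with an estimated correlation.

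Energy and stress genes rose too. Of the Msn2/4 stress genes 27 of 28 rose and 0 fell (27 and 0 adjusted over the list alone), with XBP1 (3.75), HSP26 (3.33), GLK1 (3.24) and HSP12 (2.70) (HSP12 3.54 without wild-type array 1). The stress list gave adjusted p = 1.6e-09, and 0.16 with an estimated correlation. Of the glycogen and trehalose genes 19 of 20 rose and 0 fell (19 and 0 adjusted over the list alone), with GPH1 (3.71), GAC1 (2.51), GLC3 (2.39) and GLG2 (2.05). The glycogen list gave adjusted p = 4.9e-07, and 0.21 with an estimated correlation. Of the TCA cycle genes 14 of 16 rose and 2 fell (14 and 2 adjusted over the list alone), with LSC2 (2.497), ACO1 (1.496), SDH2 (1.49) and IDH1 (1.47). The TCA cycle list gave adjusted p = 5.7e-04, and 0.55 with an estimated correlation. Of the respiratory chain genes 22 of 34 rose and 1 fell (22 and 1 adjusted over the list alone), with NDE2 (3.68), COX5B (2.70), CYC7 (2.36) and NDI1 (1.17). The respiratory chain list gave adjusted p = 3.1e-04, and 0.59 with an estimated correlation. Of the retrograde response genes 5 of 7 rose and 0 fell (5 and 0 adjusted over the list alone). The retrograde list gave adjusted p = 0.023, and 0.51 with an estimated correlation. These lists also stood higher on wild-type array 1 than on the other wild-type arrays, by 0.32, 0.40, 0.45, 0.26 and 1.05. Of the ribosome biogenesis genes 1 of 55 rose and 45 fell (1 and 45 adjusted over the list alone), with SPB4 (−1.07), RPA43 (−0.99), NOC3 (−0.92) and UTP15 (−0.90). The ribosome biogenesis list gave adjusted p = 1.5e-04, and 0.67 with an estimated correlation. Its median on wild-type array 1 was −0.47 relative to the other wild-type arrays. Of the cytosolic ribosomal proteins 2 of 127 rose and 43 fell (2 and 34 adjusted over the list alone), with RPS14B (−1.27) and RPS9A (−1.11). The ribosomal protein list gave adjusted p = 0.023, and 0.67 with an estimated correlation. Their median of −0.09 equalled that of all genes, −0.09, and the call ended without wild-type array 1 (adjusted p = 0.12), hdac array 1 (adjusted p = 0.051) or hdac array 2 (adjusted p = 0.055), and under quantile normalization.

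Of the Gcn4 genes 16 of 31 rose and 5 fell (16 and 5 adjusted over the list alone), with SNO1 (5.64), SNZ1 (3.98), HIS4 (2.90) and ARG1 (1.95). The Gcn4 list gave adjusted p = 0.0025, and 0.37 with an estimated correlation. Of the phospholipid genes 9 of 13 rose and 2 fell (9 and 2 adjusted over the list alone), with INO1 (4.18), OPI3 (1.64) and CHO1 (0.95) rising and INO2 (−0.75) falling. The phospholipid list gave adjusted p = 0.0057, and 0.36 with an estimated correlation. Cell wall genes showed 11 rises and 3 falls among 20 (11 and 3 adjusted over the list alone), with PIR3 (4.65), GSC2 (2.40), KDX1 (2.17) and PST1 (1.83). The cell wall list gave adjusted p = 0.0084, and 0.36 with an estimated correlation. Of the seripauperins, anaerobically induced wall proteins, 12 of 19 rose and 0 fell (11 and 0 adjusted over the list alone), with TIR3 (3.95), TIR1 (2.26), PAU3 (1.88) and DAN1 (1.57). The seripauperin list gave adjusted p = 0.0025, and 0.51 with an estimated correlation. Its median on wild-type array 1 was −0.45 relative to the other wild-type arrays, and without it the change of 0.53 was 0.31. All 5 flocculins measured rose, also adjusted over the list alone, with FLO11 (1.78), FLO10 (1.47), FLO9 (1.44) and FLO1 (1.09). The flocculin list gave adjusted p = 0.0016, and 0.21 with an estimated correlation. The other 16 lists did not pass (adjusted p from 0.087 to 0.776), and the 7 calls that held with an estimated correlation were those of the a-cell, alpha-cell, early meiosis, DNA damage, Adr1, gluconeogenesis and beta-oxidation lists. The median, the mean and the direction of the test differed in sign for nitrogen catabolite repression, iron regulon (Aft1), COS subtelomeric family and G1 cell cycle, none of which passed. With the background as the floor, the changes were at least 1.17-fold for RGI2, at least 3.05-fold for POX1, at least 2.77-fold for HXT11, at least 11.5-fold for XBP1, at least 4.75-fold for SSP1 and at least 2.82-fold for SPS4.

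The combined mutant, with all of these mutations, was compared with the wild type. The largest rises were in the dihydroxyacetone kinase DAK2 (6.96 ± 0.074, adjusted p = 7.2e-15), PIR3 (6.62 ± 0.19), ADH2 (6.54 ± 0.17, adjusted p = 1.4e-11), SNO1 (6.26 ± 0.16), HPF1 (5.47 ± 0.17), SGA1 (5.37 ± 0.072), INO1 (5.36 ± 0.21), the thiolase POT1 (5.33 ± 0.087), which ends each round of fatty acid oxidation, and the glycogen phosphorylase GPH1 (5.27 ± 0.13). Besides the deleted BMH2, RPD3 and HDA1, the largest falls were in BNA1 (−4.15 ± 0.092, adjusted p = 3.2e-12), IMD2 (−3.46 ± 0.084), BAR1 (−3.38 ± 0.094), AFB1 (−3.31 ± 0.14), YIR042C (−2.89 ± 0.11), SST2 (−2.85 ± 0.077), which shuts off pheromone signalling, and the ferric reductase FRE4 (−2.82 ± 0.10). BMH1 fell slightly, by 0.18 ± 0.056 (adjusted p = 0.011). In all, 1657 genes rose and 2465 fell, 596 and 376 of them at least 2-fold.

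Of the Adr1-dependent genes 19 of 20 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.77. The Adr1 list gave adjusted p = 6.8e-10. After ADH2 and POT1 came ALD4 (4.45), FDH1 (4.29), ADY2 (4.17), ACS1 (3.90), POX1 (2.67), SPS19 (2.54), RGI2 (2.12), CTA1 (1.92), ETR1 (1.62), ICL2 (1.62), PIP2 (1.27), FOX2 (1.15), CIT3 (1.07), PXA1 (1.07), ADH5 (0.97), GIP2 (0.53) and GUT1 (0.47), and ATO3 (−0.01) did not pass. POX1 and RGI2 were at background in the wild type, so their rises were at least 6.15-fold and at least 4.06-fold. Of the gluconeogenesis and glyoxylate genes 10 of 11 rose and 0 fell (10 and 0 adjusted over the list alone), with ACS1, SFC1 (3.72), JEN1 (3.11) and FBP1 (3.04). The gluconeogenesis list gave adjusted p = 7.0e-07. Of the beta-oxidation genes 17 of 19 rose and 0 fell (17 and 0 adjusted over the list alone), with POT1, POX1, CRC1 (4.17) and CAT2 (2.89). The beta-oxidation list gave adjusted p = 3.3e-08. Of the sugar-use genes 13 of 14 rose and 1 fell (13 and 1 adjusted over the list alone), with MAL32 (3.66), IMA1 (2.19), MAL11 (1.90) and GAL3 (1.48). The sugar-use list gave adjusted p = 8.8e-05, and 0.077 with an estimated correlation. Of the hexose transport genes 9 of 15 rose and 1 fell (9 and 1 adjusted over the list alone), with HXT5 (3.84), HXT9 (3.66), STL1 (2.92) and HXT7 (2.65). The hexose transport list gave adjusted p = 0.0051, and 0.16 with an estimated correlation. The glycolysis and fermentation list did not pass against other genes by camera (adjusted p = 0.092), although TDH1 (3.12) and ENO1 (1.13) rose.

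**Figure D3:**
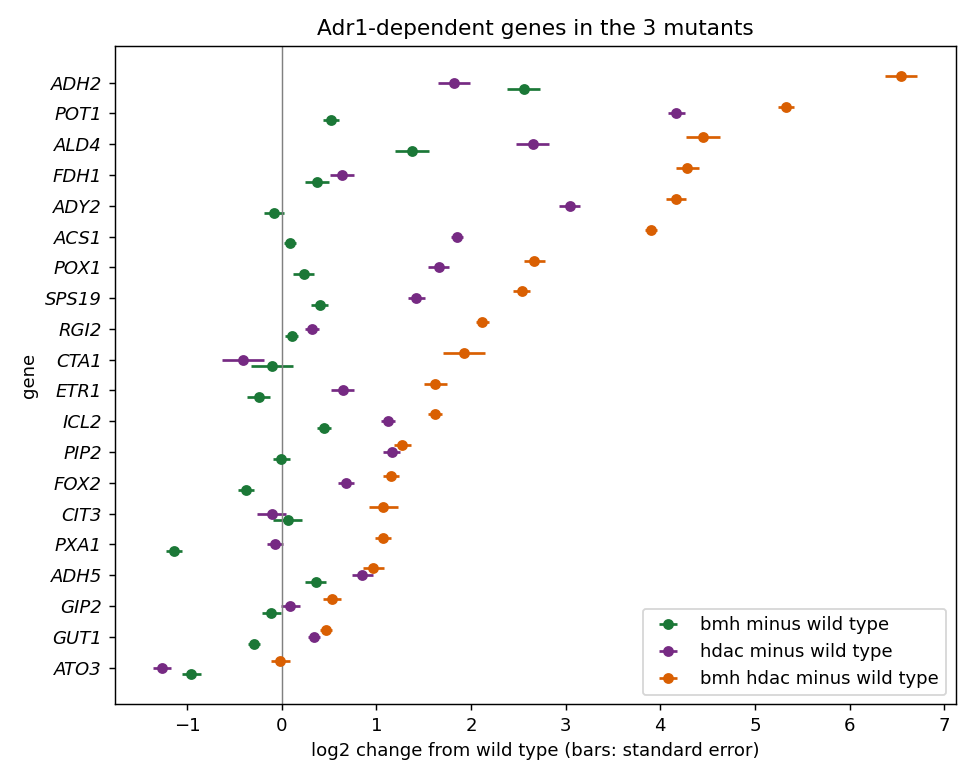
Log2 change from the wild type (horizontal axis, error bars are standard errors, n = 3 arrays per strain) of the 20 Adr1-dependent genes (vertical axis) in the bmh, hdac and combined mutants. ADH2 is at 2.56, 1.82 and 6.54, and ATO3 is the gene that is not above the wild type in the combined mutant.

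Of the Msn2/4 stress genes 26 of 28 rose and 0 fell (26 and 0 adjusted over the list alone), with HSP12 (5.01), XBP1 (4.75), MSC1 (3.93) and SPI1 (3.76) (HSP12 5.85 without wild-type array 1). The stress list gave adjusted p = 3.9e-12, and 0.099 with an estimated correlation. Of the glycogen and trehalose genes 18 of 20 rose and 0 fell (18 and 0 adjusted over the list alone), with GPH1 (5.27), GLC3 (3.07), GAC1 (2.97) and PIG1 (2.22). The glycogen list gave adjusted p = 5.5e-08, and 0.16 with an estimated correlation. Of the TCA cycle genes 13 of 16 rose and 1 fell (13 and 1 adjusted over the list alone), with LSC2 (3.23), SDH4 (1.92), SDH2 (1.87) and ACO1 (1.67). The TCA cycle list gave adjusted p = 5.8e-05, and 0.47 with an estimated correlation. Of the respiratory chain genes 21 of 34 rose and 4 fell (21 and 4 adjusted over the list alone), with NDE2 (3.96), CYC7 (3.51), COX5B (2.32) and NDI1 (1.16). The respiratory chain list gave adjusted p = 9.2e-04, and 0.57 with an estimated correlation. Of the retrograde response genes 6 of 7 rose and 1 fell (6 and 1 adjusted over the list alone). The retrograde list gave adjusted p = 0.022, and 0.48 with an estimated correlation. Of the early meiosis genes 22 of 23 rose and 0 fell (22 and 0 adjusted over the list alone), with IME2 (4.003), DMC1 (2.95), MND1 (2.87) and HOP1 (2.43). The early meiosis list gave adjusted p = 2.1e-09. Of the DNA damage genes 12 of 16 rose and 0 fell (12 and 0 adjusted over the list alone), with RNR3 (3.01), DDR48 (1.505), HUG1 (1.18) and RAD2 (1.11). The DNA damage list gave adjusted p = 1.0e-04. Of the cell wall genes 15 of 20 rose and 0 fell (15 and 0 adjusted over the list alone), with PIR3 (6.62), PST1 (2.89), KDX1 (2.52) and GSC2 (2.41). The cell wall list gave adjusted p = 7.4e-06, and 0.099 with an estimated correlation. All 5 flocculins rose, also adjusted over the list alone, with FLO11 (2.49) and FLO1 (1.98). The flocculin list gave adjusted p = 5.1e-04, and 0.15 with an estimated correlation. Of the seripauperins 12 of 19 rose and 3 fell (12 and 3 adjusted over the list alone), with TIR3 (3.99) and DAN1 (2.21). The seripauperin list gave adjusted p = 0.0053, and 0.49 with an estimated correlation. On wild-type array 1 the medians of the stress, glycogen, TCA cycle, respiratory chain, retrograde and seripauperin lists were 0.32, 0.40, 0.45, 0.26, 1.05 and −0.45 relative to the other wild-type arrays. Of the phospholipid genes 11 of 13 rose and 1 fell (11 and 1 adjusted over the list alone), with INO1 (5.36) and OPI3 (2.14). The phospholipid list gave adjusted p = 7.2e-04, and 0.19 with an estimated correlation. Of the Gcn4 genes 16 of 31 rose and 7 fell (16 and 7 adjusted over the list alone), with SNO1 (6.26) and SNZ1 (4.42). The Gcn4 list gave adjusted p = 0.0038, and 0.41 with an estimated correlation. Of the marker genes 6 of 7 rose and 1 fell (6 and 1 adjusted over the list alone), with HIS3 (4.73), LEU2 (1.77) and HO (0.90) rising and CAN1 (−1.08) falling. The marker list gave adjusted p = 0.012, and 0.099 with an estimated correlation.

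Ribosome biogenesis genes fell, 0 of 55 measured genes rose and 49 fell (0 and 50 adjusted over the list alone), with SPB4 (−1.49), NOC3 (−1.20), UTP15 (−1.16) and RLP7 (−0.99). The ribosome biogenesis list gave adjusted p = 5.5e-05, and 0.59 with an estimated correlation. On wild-type array 1 it stood at −0.47, and without that array the change of −0.54 was −0.68. Ribosomal proteins fell too, 2 of 127 measured genes rose and 81 fell (1 and 77 adjusted over the list alone), with RPS9A (−1.33) and RPL22B (−0.94). The ribosomal protein list gave adjusted p = 4.4e-04, and 0.49 with an estimated correlation. These medians of −0.54 and −0.18 compare with −0.13 for all genes. The a-cell markers fell in part: 0 of 7 measured genes rose and 6 fell (0 and 7 adjusted over the list alone), with BAR1 (−3.38), MFA1 (−2.71), STE6 (−2.31) and STE2 (−1.85). The a-cell list gave adjusted p = 0.0015. The alpha-cell list did not pass against other genes by camera (adjusted p = 0.59). SAG1 (1.56) rose and MF(ALPHA)1 was at background in both strains. HMRA1 measured 7.66 ± 0.066 in the combined mutant and 7.93 ± 0.14 in the wild type, a fall of 0.27 (adjusted p = 0.013), against 3.49 ± 0.048 in the hdac mutant. HMRA2, read by a shared probe set and chosen after the values were seen, changed by −1.19 (adjusted p = 5.6e-07) in the combined mutant and by 1.60 (adjusted p = 5.4e-08) in the hdac mutant. Of the pheromone response and mating genes 3 of 19 rose and 15 fell (3 and 15 adjusted over the list alone), with SST2 (−2.85), FUS1 (−2.38), GPA1 (−1.74) and STE12 (−1.44). The pheromone list gave adjusted p = 0.020, and 0.099 with an estimated correlation. The other 16 lists did not pass (adjusted p from 0.0769 to 0.903), and 6 calls held with an estimated correlation, those of the Adr1, gluconeogenesis, beta-oxidation, early meiosis, DNA damage and a-cell lists. The median, the mean and the direction of the test differed in sign for iron regulon (Aft1) and alpha-cell markers, none of which passed. With the background as the floor, the changes were at least 23-fold for XBP1.

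**Figure D4:**
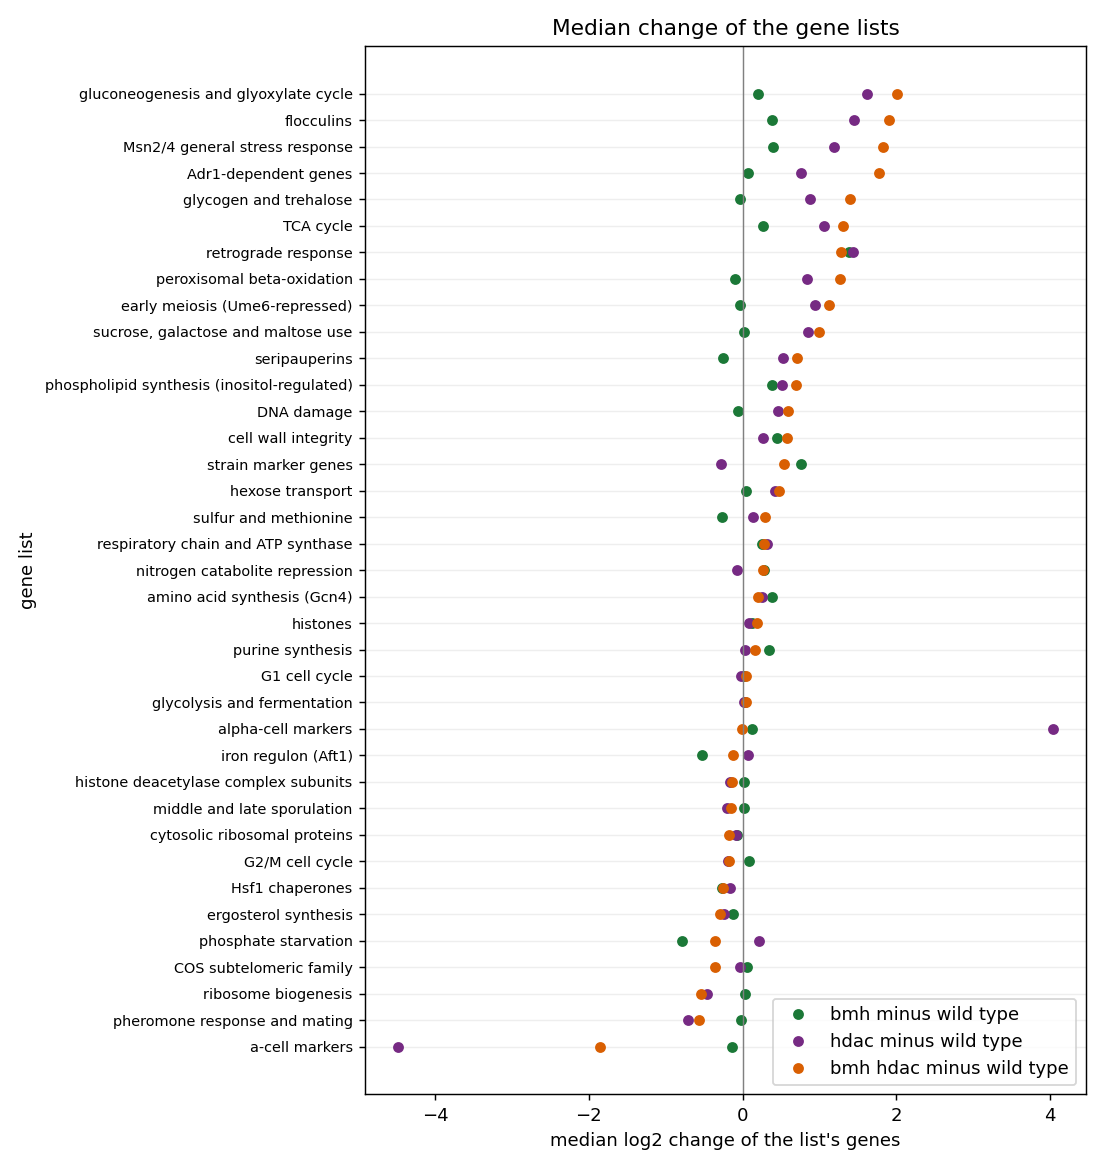
Median log2 change from the wild type (horizontal axis) of the genes of each gene list reported (vertical axis) in the bmh, hdac and combined mutants; points are medians over the measured genes. The Adr1-dependent genes are at 0.08, 0.76 and 1.77, and the alpha-cell markers are high in the hdac mutant alone, at 4.03.

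The combined mutant was then compared with the bmh mutant, which gives the effect of losing the deacetylases where 14-3-3 function is already reduced. HMLALPHA1 was at background in both strains, while HMRA1 (−0.32, adjusted p = 0.0049) and HMRA2 (−1.17, adjusted p = 7.6e-07) fell. DAK2 (5.67 ± 0.074, adjusted p = 1.5e-13), GPH1 (5.05 ± 0.13), INO1 (4.84 ± 0.21), POT1 (4.80 ± 0.087) and SGA1 (4.64 ± 0.072) rose most, and apart from the deleted genes BNA1 (−4.41 ± 0.092, adjusted p = 4.1e-12), BAR1 (−3.27 ± 0.094) and AFB1 (−3.13 ± 0.14) fell most. Of the 4088 genes changed, 1639 rose and 2449 fell, 549 and 268 of them at least 2-fold. All 20 Adr1-dependent genes rose, also adjusted over the list alone, with a median of 2.02. The Adr1 list gave adjusted p = 4.8e-11. The rises ran from POT1 over ADY2 (4.25), ADH2 (3.99), FDH1 (3.91), ACS1 (3.81), ALD4 (3.08), POX1 (2.44), PXA1 (2.22), SPS19 (2.13), CTA1 (2.03), RGI2 (2.01), ETR1 (1.87), FOX2 (1.53), PIP2 (1.28), ICL2 (1.17), CIT3 (1.01), ATO3 (0.94), GUT1 (0.76) and GIP2 (0.64) to ADH5 (0.61). Of the beta-oxidation genes 17 of 19 rose and 0 fell (17 and 0 adjusted over the list alone), with POT1, POX1, CRC1 (3.08) and CAT2 (2.63). The beta-oxidation list gave adjusted p = 1.4e-09. Of the early meiosis genes 22 of 23 rose and 1 fell (22 and 1 adjusted over the list alone), with IME2 (3.33), MND1 (2.91), DMC1 (2.67) and ZIP1 (2.33). The early meiosis list gave adjusted p = 1.3e-09. Of the DNA damage genes 13 of 16 rose and 1 fell (13 and 1 adjusted over the list alone), with RNR3 (3.08) and HUG1 (2.10). The DNA damage list gave adjusted p = 1.4e-04. Phosphate starvation genes, which had fallen in the bmh mutant, were higher: 9 of 13 measured genes rose and 1 fell (9 and 1 adjusted over the list alone), with PHO5 (4.13), PHO89 (3.42), SPL2 (2.38) and VTC3 (0.98). The phosphate list gave adjusted p = 0.0035, and 0.53 with an estimated correlation. Iron genes were higher as well, 10 of 17 measured genes rose and 2 fell (10 and 2 adjusted over the list alone), with FIT3 (3.04), SIT1 (1.81), FIT1 (1.56) and FIT2 (1.40). The iron list gave adjusted p = 0.018, and 0.54 with an estimated correlation. Of the sulfur genes 16 of 24 rose and 2 fell (16 and 2 adjusted over the list alone), with STR3 (2.73), MET2 (1.78), SUL1 (1.68) and MET13 (1.57). The sulfur list gave adjusted p = 0.0025, and 0.59 with an estimated correlation. Of the seripauperins 13 of 19 rose and 0 fell (13 and 0 adjusted over the list alone), with TIR3 (4.24), TIR1 (3.35) and DAN1 (2.28). The seripauperin list gave adjusted p = 1.9e-04, and 0.47 with an estimated correlation. The a-cell markers fell, 0 of 7 measured genes rose and 6 fell (0 and 6 adjusted over the list alone), with BAR1 (−3.27), MFA1 (−2.13), STE6 (−1.97) and STE2 (−1.74). The a-cell list gave adjusted p = 0.0033, and 0.067 with an estimated correlation. Of the pheromone response genes 3 of 19 rose and 13 fell (3 and 13 adjusted over the list alone), with SST2 (−2.63), FUS1 (−2.40), GPA1 (−1.73) and STE12 (−1.40). The pheromone list gave adjusted p = 0.045, and 0.15 with an estimated correlation. The pheromone call ended without wild-type array 1 (adjusted p = 0.068), wild-type array 3 (adjusted p = 0.054), bmh array 3 (adjusted p = 0.054) or hdac array 2 (adjusted p = 0.051). With only the bmh and combined arrays in the fit it ended as well, unpaired (adjusted p = 0.075) or paired by number (adjusted p = 0.095). Lists that moved as against the wild type were upward gluconeogenesis (adjusted p = 7.6e-05, and 0.067 with an estimated correlation; JEN1 3.45) and sugar use (adjusted p = 7.6e-05, and 0.070 with an estimated correlation; MAL32 3.02). Upward too were hexose transport (adjusted p = 0.0011, and 0.15 with an estimated correlation; HXT5 3.77) and the TCA cycle (adjusted p = 0.0011, and 0.56 with an estimated correlation; LSC2 2.25), then the stress response (adjusted p = 2.7e-10, and 0.15 with an estimated correlation; HXK1 3.86). Glycogen (adjusted p = 4.7e-08, and 0.18 with an estimated correlation; GPH1) and phospholipid synthesis (adjusted p = 0.010, and 0.45 with an estimated correlation; INO1) followed. Flocculins (adjusted p = 0.0011, and 0.18 with an estimated correlation; FLO11 1.99) and the cell wall (adjusted p = 0.021, and 0.47 with an estimated correlation; PIR3 2.41) were up as well. Ribosome biogenesis was down (adjusted p = 3.6e-06, and 0.59 with an estimated correlation; SPB4 −1.48). In total 20 lists passed and 18 did not (adjusted p from 0.0507 to 0.979). Median, mean and test direction differed in sign for Hsf1 chaperones, retrograde response, amino acid synthesis (Gcn4) and alpha-cell markers, which did not pass. With the background as the floor, the changes were at least 17.7-fold for HDA1 and at least 48.3-fold for RPD3.

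The combined mutant was compared with the hdac mutant, which varies 14-3-3 function without the deacetylases. Mating-type transcripts also differed, and marker genotype may have. MFA2 (5.49 ± 0.080, adjusted p = 1.4e-13), STE2 (4.89 ± 0.075), ADH2 (4.72 ± 0.17, adjusted p = 1.2e-09), HIS3 (4.23 ± 0.063) and the stationary-phase gene SPG4 (4.18 ± 0.17) rose most, and besides the deleted BMH2 the largest falls were in MF(ALPHA)1 (−7.83 ± 0.078), HMLALPHA1 (−6.66 ± 0.060), AFB1 (−5.34 ± 0.14) and STE3 (−4.69 ± 0.096). Of the 1982 genes changed, 954 rose and 1028 fell, 109 and 76 of them at least 2-fold; with array weights the count was 3213 and at adjusted p under 0.01 it was 1279. Of the Adr1-dependent genes 17 of 20 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.14. The Adr1 list gave adjusted p = 9.3e-14. After ADH2 the rises were in FDH1 (3.65), CTA1 (2.33), ACS1 (2.05), RGI2 (1.80), ALD4 (1.80), ATO3 (1.25), CIT3 (1.18), POT1 (1.16), PXA1 (1.15), ADY2 (1.13), SPS19 (1.11), POX1 (1.01), ETR1 (0.98), ICL2 (0.49), FOX2 (0.48) and GIP2 (0.44), and GUT1 (0.13), PIP2 (0.11) and ADH5 (0.11) did not pass. Of the beta-oxidation genes 14 of 19 rose and 0 fell (14 and 0 adjusted over the list alone), with CTA1, POT1, PXA1 and ECI1 (1.20). The beta-oxidation list gave adjusted p = 4.1e-08. All 7 a-cell markers rose (adjusted p = 9.8e-12) and all 4 alpha-cell markers fell (adjusted p = 1.6e-06), also adjusted over the list alone. Of the marker genes 5 of 7 rose and 0 fell (5 and 0 adjusted over the list alone), with HIS3 (4.23), LEU2 (3.62), URA3 (1.40) and ADE2 (0.81). The marker list gave adjusted p = 1.9e-05. Of the cell wall genes 15 of 20 rose and 0 fell (16 and 0 adjusted over the list alone), with PIR3 (1.97), PRM5 (1.29), PST1 (1.06) and CHS1 (0.90). The cell wall list gave adjusted p = 8.8e-07, and 0.091 with an estimated correlation. Of the stress genes 21 of 28 rose and 1 fell (21 and 1 adjusted over the list alone), with RTN2 (2.38), HSP12 (2.31), MSC1 (2.26) and SPI1 (1.56). The stress list gave adjusted p = 1.4e-08, and 0.19 with an estimated correlation. Of the gluconeogenesis genes 8 of 11 rose and 1 fell (8 and 1 adjusted over the list alone), with ACS1, PCK1 (1.07) and FBP1 (0.99) rising and CIT2 (−1.27) falling. The gluconeogenesis list gave adjusted p = 3.2e-04, and 0.076 with an estimated correlation. Of the phosphate starvation genes 1 of 13 rose and 8 fell (1 and 9 adjusted over the list alone), with PHM6 (−2.37), PHO11 (−1.32), SPL2 (−1.12) and VTC3 (−0.57). The phosphate list gave adjusted p = 0.0024, and 0.44 with an estimated correlation. The 8 falls were 5 without combined array 2 or 3 or hdac array 1 or 3. Of the COS family, subtelomeric genes with near-identical copies, 1 of 9 rose and 6 fell (1 and 6 adjusted over the list alone), with COS8 (−1.66), COS2 (−1.42), COS10 (−1.05) and COS7 (−0.91). The COS list gave adjusted p = 0.0052, and 0.19 with an estimated correlation. The other lists that passed upward were sugar use (adjusted p = 0.016, and 0.23 with an estimated correlation; MAL32 1.54), the TCA cycle (adjusted p = 0.0052, and 0.60 with an estimated correlation; LSC2 0.73) and glycogen (adjusted p = 0.0011, and 0.42 with an estimated correlation; GPH1 1.56). Early meiosis (adjusted p = 4.1e-04, and 0.063 with an estimated correlation; IME1 1.13), sporulation (adjusted p = 0.0024, and 0.100 with an estimated correlation; SPO21 0.89) and phospholipid synthesis (adjusted p = 0.0082, and 0.35 with an estimated correlation; INO1 1.18) passed upward. So did nitrogen catabolite repression (adjusted p = 0.010, and 0.22 with an estimated correlation; DIP5 2.49) and flocculins (adjusted p = 0.0013, and 0.19 with an estimated correlation; FLO1 0.89). Downward were ribosomal proteins (adjusted p = 5.1e-04, and 0.50 with an estimated correlation; RPS27A −0.29) and ergosterol synthesis (adjusted p = 0.018, and 0.29 with an estimated correlation; ERG27 −0.71). In total 20 lists passed and 18 did not (adjusted p from 0.0562 to 0.921). Median, mean and test direction differed in sign for respiratory chain and ATP synthase, retrograde response, purine synthesis and seripauperins, which did not pass. With the background as the floor, the changes were at least 183-fold for BMH2, at least 182-fold for MF(ALPHA)1 and at least 81.3-fold for HMLALPHA1.

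The interaction asks where the combined mutant departed from the sum of the effects of the bmh and hdac mutants on the log2 scale. For ADH2 those effects sum to less than the 6.54 measured, with an interaction of 2.17 ± 0.24 (adjusted p = 4.8e-05), and FDH1, a formate dehydrogenase, had 3.28 ± 0.17 (adjusted p = 9.5e-08). The other largest positive values were in mating genes, MFA2 (5.63 ± 0.11), STE2 (5.00 ± 0.11) and AGA2 (4.03 ± 0.11), and large negative ones were in AFB1 (−5.16 ± 0.20), STE3 (−4.93 ± 0.14) and MF(ALPHA)2 (−3.27 ± 0.17). HMRA1 was positive and MF(ALPHA)1 and HMLALPHA1 negative, but HMRA1 was at background in the hdac mutant and the others were at background in the other 3 strains, so no size is given for them here. Of 5448 genes, 1289 had an interaction, 671 positive and 618 negative, and 120 and 99 of them were at least 2-fold. Without wild-type array 1 the count was 1962, with array weights 2233 and at adjusted p under 0.01 738.

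Of the Adr1-dependent genes, 16 had a positive interaction and 0 a negative one, also adjusted over the list alone, with a median of 0.99 (adjusted p = 2.7e-12). Besides FDH1 and ADH2 these were CTA1 (2.44), PXA1 (2.29), ATO3 (2.21), ACS1 (1.96), RGI2 (1.70), ETR1 (1.23), ADY2 (1.21), CIT3 (1.11), FOX2 (0.86), POX1 (0.78), SPS19 (0.71), POT1 (0.63), GIP2 (0.55) and GUT1 (0.42), and ALD4 (0.43), PIP2 (0.12), ICL2 (0.05) and ADH5 (−0.25) did not pass. POX1 and RGI2 were at background in the wild type, so their sizes here are not exact. Beta-oxidation genes had 12 positive and 1 negative values (15 and 1 adjusted over the list alone; adjusted p = 1.2e-07), with CTA1, PXA1, FAA2 (1.48) and ECI1 (1.16). The early meiosis list was positive as well (adjusted p = 0.0025, and 0.15 with an estimated correlation), with IME1 (2.10) and ZIP1 (1.30) and REC104 (−0.91), and so was hexose transport (adjusted p = 0.013, and 0.28 with an estimated correlation), with HXT2 (1.71), HXT4 (1.55) and HXT7 (1.07). Iron genes, 9 of 17 positive and 0 negative (10 and 0 adjusted over the list alone; adjusted p = 3.5e-04, and 0.32 with an estimated correlation), included FET3 (2.97), FTR1 (1.93), SIT1 (1.32) and FIT3 (1.01). The iron list stood 0.35 higher on wild-type array 1, and without it the median of 0.65 was 0.39. Phosphate genes (adjusted p = 0.0011, and 0.44 with an estimated correlation) included PHO5 (2.32), SPL2 (2.14), PHO11 (1.34) and VTC3 (0.77). Gcn4 genes were negative, 20 of 31 against 3 positive (22 and 4 adjusted over the list alone; adjusted p = 1.7e-07, and 0.17 with an estimated correlation), with HIS4 (−2.64), SNO1 (−2.32), ARG1 (−2.14) and SNZ1 (−1.47). So were the purine list (adjusted p = 5.5e-05, and 0.17 with an estimated correlation), with ADE17 (−2.33), IMD2 (−1.72), ADE1 (−1.22) and MTD1 (−0.94), and the retrograde list (adjusted p = 0.0036, and 0.42 with an estimated correlation), with CIT2 (−2.67), IDH2 (−1.54), IDH1 (−1.31) and ACO1 (−0.92). The retrograde list stood 1.05 higher on wild-type array 1. Calls of single genes named here that ended when 1 array was left out were those of ACO1 (11 of 12 arrays; adjusted p = 0.089 without wild-type array 2) and IDH1 (2 of 12 arrays; adjusted p = 0.054 without bmh array 2). The Adr1, beta-oxidation, a-cell and alpha-cell calls were the 4 that held with an estimated correlation. The Adr1 and beta-oxidation lists share genes, CTA1 and PXA1 among them, so these calls are not independent.

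The a-cell list was positive (adjusted p = 3.7e-14) and the alpha-cell list negative (adjusted p = 1.0e-07). The respiratory chain list was negative (11 of 34 genes negative and 0 positive; adjusted p = 1.7e-05, and 0.55 with an estimated correlation), with CYC7 (−1.19) and CYC1 (−0.65); 28 genes were negative without wild-type array 1. The COS list was negative (5 of 9 genes negative and 0 positive; adjusted p = 0.0023, and 0.17 with an estimated correlation), with COS2 (−1.48) and COS8 (−1.46). The sulfur list was positive (8 of 24 genes positive and 2 negative; adjusted p = 0.0053, and 0.64 with an estimated correlation), with MET14 (1.38) and MET3 (1.28). The list stood 0.61 higher on wild-type array 1, and without it the median of 0.52 was 0.26. The sporulation list was positive (8 of 23 genes positive and 0 negative; adjusted p = 0.017, and 0.23 with an estimated correlation), with CRR1 (1.00) and SPR1 (0.92). SPS4 was at background in the hdac and combined mutants, so no size is given for it. The gluconeogenesis list was positive (7 of 11 genes positive and 2 negative; adjusted p = 0.030, and 0.31 with an estimated correlation), with PCK1 (0.87) and JEN1 (0.86), a call that ended without wild-type array 1 (adjusted p = 0.060) or bmh array 1 (adjusted p = 0.056; 4 genes positive). The glycogen list was positive (7 of 20 genes positive and 1 negative; adjusted p = 0.013, and 0.57 with an estimated correlation), with GPH1 (1.34) and PIG1 (0.97), until wild-type array 1 was left out (adjusted p = 0.086). The ribosome biogenesis list was called negative with few of its genes (3 of 55 genes negative and 0 positive; adjusted p = 0.032, and 0.85 with an estimated correlation), KRR1 (−1.12) and SPB1 (−1.03) among them; 5 were negative without wild-type array 3. The call ended without wild-type array 1 (adjusted p = 0.96), bmh array 1 (adjusted p = 0.084), combined array 3 (adjusted p = 0.075) or hdac array 2 (adjusted p = 0.071). The sugar-use list was positive (3 of 14 genes positive and 0 negative; adjusted p = 0.032, and 0.34 with an estimated correlation), with MAL32 (0.90), until wild-type array 2 (adjusted p = 0.14) or combined array 3 (adjusted p = 0.060) was left out. The respiratory chain, COS, glycogen, ribosome biogenesis and seripauperin lists stood apart on wild-type array 1 by 0.26, 0.39, 0.40, −0.47 and −0.45. The seripauperin list was positive (5 of 19 genes positive and 0 negative; adjusted p = 0.025, and 0.64 with an estimated correlation), with TIR1 (1.08); 11 genes were positive without wild-type array 1, and 1 to 3 without any other array but wild-type array 3 or hdac array 1. The call ended without wild-type array 2 (adjusted p = 0.11), combined array 3 (adjusted p = 0.051) or hdac array 2 (adjusted p = 0.082). In total 20 lists passed and 18 did not (adjusted p from 0.0528 to 0.971). Median, mean and test direction differed in sign for cytosolic ribosomal proteins, pheromone response and mating and strain marker genes, which did not pass.

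Changes shared by the bmh and hdac mutants were counted against the same wild-type arrays. Both mutants rose at 430 genes and fell at 477, and 413 genes moved in opposite directions; lists drawn independently would share 241 and 389. At 2-fold or more the counts were 46 and 15, against 7.84 and 2.97, and genes that rose in both include PIR3, HSP12, SNO1, HPF1, ADE17 and ADH2. Without wild-type array 1 the counts were 666 and 749, against 364 and 550. The log2 changes of the mutants had a covariance of 0.0828 across genes, against 0.00485 in 100 simulations of unchanged groups with shared controls, a difference of 0.0779; the Pearson correlation was 0.242, against 0.499 in the simulations. The 3 wild-type arrays are too few to split into separate controls for each mutant. In comparisons with no shared arrays, the effect of the bmh mutations with and without HDA1 and RPD3 correlated at 0.415 across genes and the effect of the deacetylase deletions with full and reduced 14-3-3 function at 0.834; genes are not independent replicates.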

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

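Differences between groups drew attention where the combined mutant departed from the sum of the other mutants: 1289 genes had an interaction. The largest were MFA2 (5.63), STE2 (5.00), HMRA1 (4.12), AGA2 (4.03), FDH1 (3.28), MF(ALPHA)1 (−7.90), HMLALPHA1 (−6.65), AFB1 (−5.16), STE3 (−4.93) and MF(ALPHA)2 (−3.27). The values of HMRA1, MF(ALPHA)1 and HMLALPHA1 rest on means at background and have no exact size. The 20 lists that passed drew attention for the same reason, with median interactions of 0.99 for Adr1-dependent genes, 0.47 for gluconeogenesis, 0.63 for beta-oxidation, 0.22 for sugar use, 0.26 for hexose transport, −0.27 for the respiratory chain, 0.27 for glycogen, −0.14 for ribosome biogenesis, 0.32 for early meiosis, 0.18 for sporulation, 0.32 for phosphate, −0.92 for the retrograde response, −0.38 for Gcn4 genes, 0.52 for sulfur, −0.41 for purines, 0.65 for iron, 2.74 for a-cell and −4.10 for alpha-cell markers, 0.29 for seripauperins and −0.63 for COS genes; 16 of these calls were lost with an estimated correlation. Without wild-type array 1 the medians of ribosome biogenesis, sulfur and iron were 0.01, 0.26 and 0.39; without wild-type array 2 those of ribosome biogenesis and seripauperins were −0.21 and 0.19; without wild-type array 3 those of ribosome biogenesis and hexose transport were −0.25 and 0.14. In data not otherwise described, 11 of the 218 probe sets without a gene name changed at least 2-fold in the bmh mutant (10 rose, 1 fell), 50 in the hdac mutant (42 and 8) and 65 in the combined mutant (51 and 14).

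The relabelling test, chosen before the result was seen, cannot judge chance, as mixed groups put strain differences into the spread. In each pairwise comparison only the real one of 10 splits reached the real count, and the others gave 0. 10 splits also cannot give a share under 0.05. For the interaction, 4 of 100 drawn assignments, the real one included, reached 1289, and the highest other count was 1880. The others that reached 1289 put 5 of the 6 hdac and combined arrays on 1 side, so their counts hold strain differences.

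The Adr1-dependent genes rose more in the combined mutant than the bmh and hdac effects add up to; the 3 tests here were chosen after the result was seen. Compression of small rises near background was excluded: the 12 of 20 members at least 2 log2 units above it in every strain had a median interaction of 1.04, and 8 of them were positive. An effect of wild-type array 1 was excluded, as the median without it was 1.01. A share of the mating type stays open: 0 hdac arrays had MATa1 above background, so no hdac array of the wild type's mating type was used here. Joint control by 14-3-3 proteins and deacetylases would give this pattern, though no test here separates it from mating type.

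Alpha-cell markers were high and a-cell markers low on the hdac arrays; the 4 tests here were chosen after the result was seen. Sizes that involve values at background are lower bounds. Loss of silencing at HML in a cells, which would leave MATa1 on, was excluded, as MATa1 changed by −3.80 or beyond, and alpha1 was at background in the combined mutant (3.82), which lacks the same deacetylases. Arrays of the wild type or bmh mutant under the hdac label were excluded, as HDA1 and RPD3 lay at least 4.09 lower. Arrays of the combined mutant were excluded, as BMH2 on the hdac arrays lay at most 0.063 from the wild-type mean. A strain outside the 4 with the same deletions stays open. A MATalpha allele in the hdac strain fits the alpha1 rise of at least 6.34. Comparisons with the hdac mutant would then mix genotype with mating type.

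Wild-type array 1 stood apart from wild-type arrays 2 and 3; the scaling test was chosen before the result was seen, and those of RNA mixing and culture state after it. A curve on signal level explained 0.574% of the variance of the difference. This cannot exclude array scaling or background, as RMA had already evened out the signal levels of the arrays. RNA of a mutant mixed in was excluded, as HIS3 and MF(ALPHA)1 differed by at most 0.14. Another state of that culture fits, as 11 of 38 lists lay outside nearly the whole range of 10000 random lists matched for signal.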

How the results depend on the processing

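Among 1003 values of named genes, none that was called changed direction in any setting; some that were not called did, such as CIT3 in the bmh mutant (0.06, and −0.12 without wild-type array 1). Leaving out wild-type array 1 left 997 on the same side of the threshold, and quantile normalization 989. Counts moved by over 1.5 times in these cases. For bmh against wild type 1742 became 1093 with only the 2 groups compared and 1076 at adjusted p under 0.01. For combined against hdac 1982 became 3213 with array weights and 1279 at 0.01. The interaction count of 1289 became 2233 with array weights, 738 at 0.01 and 1962 without wild-type array 1. Fits of 2 groups lowered the counts against the wild type but raised those of combined against bmh (4088 to 4369) and against hdac (1982 to 2735). Fewer arrays alone therefore do not account for the fall to 1093. The pooled spread tends to understate that of the wild type and overstate those of the mutants. The strict limit lowers counts by construction; for array weights, which gave wild-type array 1 a weight of 0.0863, and for the other cases the cause was not tested. Leaving out each array in turn gave 1319 to 2351 (bmh), 3630 to 4202 (hdac), 3869 to 4361 (combined), 3829 to 4381 (combined against bmh), 1569 to 2766 (combined against hdac) and 1051 to 1962 (interaction). The overlap of bmh and hdac rises, 430, was 46 at 2-fold or more and 666 without wild-type array 1; that of falls, 477, was 15 and 749. With an estimated correlation 20 of 20, 15 of 22, 16 of 22, 16 of 20, 15 of 20 and 16 of 20 list calls were lost in the same order of comparisons. With fry, which asks whether the genes of a list changed rather than changed more than others, 3 (TCA cycle, sulfur, seripauperins), 0, 0, 0, 1 (TCA cycle) and 4 (glycogen, ribosome biogenesis, sulfur, seripauperins) were lost and 3, 11, 14, 13, 6 and 8 gained.

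With the replicate number as a block the counts were 1571, 3842, 4069, 4019, 1863 and 1174. No list call was lost under this block. In the other comparisons some same-numbered arrays correlated below 0.1, down to −0.176, and their samples share only a number. With the bmh and combined arrays alone and paired, an alternative added after the data were seen, 4399 genes changed against 4369 for these arrays unpaired, all 817 calls of at least 2-fold were kept, and no call of a named gene changed. The pheromone list lost its call both unpaired (adjusted p = 0.075, added after the data were seen) and paired (adjusted p = 0.095), so the loss is not due to the block alone; no other list call changed in these fits. Filters and centring on S. pombe probe sets were planned and not run, because the table used here gives none; log2(value+16) did not apply to log values. Filters on the level of deleted genes, the Adr1-dependent genes well above background (1.04) and the interaction without mating genes (1265) were added after the data were seen.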

Other observations

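Genes for NAD synthesis from tryptophan were looked at after the values were seen and were not tested as a group. In the hdac mutant BNA1 (−4.66), BNA2 (−1.81), BNA6 (−1.86), BNA4 (−0.47), BNA7 (−0.47) and BNA5 (−0.31) and the nicotinate transporter TNA1 (−1.94) fell and BNA3 (0.73) rose. In the combined mutant BNA1 (−4.15), BNA6 (−2.001), TNA1 (−1.93), BNA7 (−1.58), BNA4 (−1.56), BNA5 (−1.06) and BNA2 (−0.58) fell and BNA3 (0.81) rose. In the bmh mutant BNA7 (−1.14), BNA5 (−0.77) and TNA1 (−0.29) fell and BNA1 (0.26) and BNA2 (0.37) rose.

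Lists that did not pass in the hdac and combined mutants, in this order, against the wild type still held called genes: the histones (adjusted p = 0.29, 2 rose and 1 fell; adjusted p = 0.077, 6 and 1), the G1 list (adjusted p = 0.78, 3 rose and 3 fell; adjusted p = 0.43, 6 and 3), the G2/M list (adjusted p = 0.45, 3 rose and 6 fell; adjusted p = 0.61, 2 and 6) and the deacetylase complex subunits (adjusted p = 0.61, 5 rose and 10 fell; adjusted p = 0.90, 6 and 10).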
